A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

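Per the labels, RNA was extracted with TRIzol, messenger RNA was selected by poly(A), libraries were made with the NEBNext Ultra RNA kit, which does not mark the strand, and sequencing ran on a NovaSeq 6000. The 10 libraries were grouped by strain and temperature as the labels give them: XH7 at 30 °C (n = 2), XH7 at 50 °C (n = 2), Z100 at 30 °C (n = 3) and Z100 at 50 °C (n = 3). The labels give a heat shock of 1 h at 50 °C.

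The authors deposited raw counts per gene, whole numbers with 6059 genes and 51901045 to 81442848 counts per library. The deposited FPKM values, per the labels of the tables, are counts scaled to gene length in kilobases and to the total of each library. As a check, the length implied by the deposited counts and FPKM values varied by a median of 0.194% over libraries in 5386 genes with high counts, and its median ratio to the annotated gene length was 1.0018. The deposited transcript counts were the same as the gene counts in 100% of values, so they were not used as a second measurement. The aligner and the counting tool are not given in the sources used here. Genes were placed on the R64 genome by the positions in the tables: 6051 matched an annotated gene, 486 of these under another identifier, and 5936 code for proteins. In all, 260 genes overlap another gene and 310 have a near-identical copy (BLAST 2.17.0, at least 95% identity over at least 50% of the length), whose counts are less certain. The 3 genes whose lines are empty are not analysed here.

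Counts were tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): scaling factors by TMM, the low-count filter of the function filterByExpr by group, which left 6015 genes, and a quasi-likelihood F test in a single model of 4 group means over all 10 libraries. The biological coefficient of variation was 0.238, with 6 residual and 3.95 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes, and a gene was called at an adjusted p under 0.05. There were 5 comparisons: heat in XH7, heat in Z100, Z100 against XH7 at 30 °C and at 50 °C, and the difference between the heat responses (interaction). Standard errors were computed as the log2 fold change divided by the square root of F. In tables of log2 CPM the prior count was 2.

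For 40 gene lists, fixed from general knowledge of yeast genes, camera tested each list on log2 CPM with a preset correlation between genes of 0.01, and again with a correlation estimated from the data. Members called were counted over all genes and with p-values adjusted over the list alone. Chromosomes were tested by the same 2 camera settings, as medians relative to the median of all genes and as rolling medians of 25 genes. Genes seen in 1 strain were those with at most 3 counts in every library of 1 strain and at least 50 in every library of the other. A floor of 3 counts corresponds to 0.037 to 0.058 CPM in these libraries.

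The comparisons, the lists, the alternatives other than 3 and the rule for the genes that the text names were fixed before the data were examined. The rule names, per comparison: the 6 largest rises and 6 largest falls among called genes with a mean of at least 10 CPM in the higher group, a gene symbol and, except for the interaction, no overlap between libraries of the 2 groups; up to 4 called members of each described list by size of change, or up to 2 by smallest p if none was called; the anchor genes HSP104, SSA4, HSP26, HSP12, CTT1, TPS1, TPS2, PDC1, ADH1, ERG11 and HXT1; genes seen in 1 strain; and up to 3 called genes of each described chromosome. CNS1, SNL1, RPL15B, CYC1, COX5A (heat in Z100), FRE1, DAL5, HXT6, the overlapping genes and copies named beside others, and genes at the ends of chromosome runs fall outside it and were named after their values were seen.

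Alternatives were DESeq2 1.42.0, limma-voom, 4 other scalings (RLE, upper quartile, library size only, reference genes), no filter and a filter of at least 5 CPM, fits of the compared groups alone, the replicate number as a block, limma on log2 FPKM, leaving out the most abundant 1% of genes, fold thresholds, and leaving out each library in turn; where this left 1 library in a group, that library was assumed to vary like the other groups. The procedure was tested on simulated data with 50 genes changed at each fold size. At 2-fold it recovered 32% (heat in XH7, 6007 genes), 58% (heat in Z100, 6006), 38% (strains at 30 °C, 6005), 34% (strains at 50 °C, 6005) and 4% (interaction, 6008) of changed genes, and at 4-fold 92%, 96%, 96%, 80% and 72%. Of the calls, 8.2%, 6.3%, 4.8%, 3.5% and 4.3% were false in these simulations. There all groups otherwise had the same mean, and each gene had 1 spread. In the data most genes were called with heat and the spread differed between groups, so these rates may not carry over. Figures and gene maps were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.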

Results

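The series compared messenger RNA levels in 2 strains of the budding yeast Saccharomyces cerevisiae, the control strain XH7 and Z100, a strain evolved under mild heat whose genetic changes the study set out to find. Each strain was sampled at 30 °C, as the labels name it, and after 1 h of heat shock at 50 °C. XH7 had 2 libraries at each temperature and Z100 had 3, 10 in all. The protocol text says that cultures without heat shock were held in an ice-water mixture, so it stays open whether the cells labelled 30 °C were taken from a 30 °C culture, from ice water, or from both in turn. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

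The deposited gene counts summed to between 51901045 and 81442848 per library, and 6015 genes passed the filter on low counts. Replicate libraries of 1 group differed by more than counting noise in every pair. The median over genes of the SD of log2 CPM (counts scaled to a common library size) was 0.0917 in XH7 at 30 °C. It was 0.174 in Z100 at 30 °C, 0.258 in Z100 at 50 °C and 0.324 in XH7 at 50 °C. The heat-shocked libraries were thus the more variable. The gene tests used 1 spread per gene over all groups. Taken alone, this would make standard errors and p-values tend to be too small between strains at 50 °C and too large at 30 °C. However, same-numbered libraries of the 2 strains deviated together at 50 °C (correlations of 0.635 for number 1 and 0.529 for number 2). Deviations shared by both strains cancel in their difference, so the net effect at 50 °C is not known. The 10 most abundant genes held 10.6% to 18.2% of the counts at 30 °C and 18.4% to 25.4% at 50 °C. On the first principal component, with 82.6% of the variance, all 30 °C libraries lay on 1 side and all 50 °C libraries on the other. Ribosomal RNA took 0.53% of the counts in XH7 30 °C replicate 2 and at most 0.15% in the other libraries. Below, ± after a CPM value is the SD (n = 2 for XH7, n = 3 for Z100) and ± after a log2 fold change is its standard error. Adjusted p-values of genes come from edgeR's quasi-likelihood test and those of gene lists from camera.

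The heat comparison in XH7 asked how the control strain responds to heat shock. Heat shock protein genes rose by far: HSP26 (YBR072W, chromosome II 382030 to 382674), which encodes a small heat shock protein that holds unfolding proteins, went from 1.48 ± 0.22 to 28256 ± 14500 CPM, a log2 fold change of 14.22 ± 0.76. HSP12, a membrane-associated stress protein, rose by 11.16 ± 0.71, the Hsp70 chaperone gene SSA4 by 10.46 ± 0.49, the small heat shock protein gene HSP42 by 9.51 ± 0.33 and TSL1, a subunit of the trehalose synthase complex, by 9.34 ± 0.47, with adjusted p-values between 2.2e-07 and 1.3e-06 (edgeR). Genes for making ribosomes fell to low levels. ERB1 went from 190.3 ± 0.66 to 1.67 ± 1.17 CPM (log2 fold change -6.82 ± 0.89), NSR1 from 912 ± 46.7 to 9.35 ± 1.73 CPM (-6.61 ± 0.70). PUF6, DBP2 and UTP14 had log2 fold changes of -7.24, -6.62 and -6.61. SPO19 went from 11.9 ± 0.60 CPM to 0 and 4 counts in the heat-shocked libraries. CPP2, also among the 6 largest rises, was at 0 in both 30 °C libraries and at 0.032 and 20.3 CPM in the heat-shocked ones. It overlaps another gene, YDR209C, and its call ended without XH7 50 °C replicate 2 or either XH7 30 °C library (adjusted p up to 0.51, edgeR).

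By group, 22 of 24 cytosolic chaperone and Hsf1 target genes rose in XH7 (22 adjusted over the list alone), with a median log2 fold change of 5.08; HSP104, the disaggregase, rose by 7.01 ± 0.31. CNS1 and SNL1 fell (-3.26 ± 0.37 and -2.05 ± 0.18). In a list of general stress genes, assigned from general knowledge to the transcription factors Msn2 and Msn4, 28 of 29 rose (29 adjusted over the list alone, median 5.50). Among them were HSP30 (9.26 ± 0.31), TMA10 (8.85 ± 0.55) and the catalase gene CTT1 (6.27 ± 0.33). Whether these factors control each member was not tested. Of the genes of trehalose and glycogen metabolism, 17 of 18 rose (17 adjusted over the list alone, median 4.50), with TPS1 and TPS2, the 2 catalytic steps of trehalose synthesis, at 5.33 ± 0.55 and 4.55 ± 0.27 and the glycogen phosphorylase gene GPH1 at 6.85 ± 0.39. The camera adjusted p-values of these 3 lists were 7.1e-11, 3.3e-15 and 1.6e-09, each with adjusted p = 0.402 with an estimated correlation.

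Mitochondrial and secretory groups rose by less. Of the nuclear-encoded respiratory chain genes 31 of 39 rose and none fell (31 adjusted over the list alone, median 1.38), led by the cytochrome c isoform CYC7 (5.50 ± 0.35) and the external NADH dehydrogenase NDE2 (3.55 ± 0.45). Of the TCA cycle genes 15 of 18 rose and 1 fell (15 and 1 adjusted over the list alone, median 1.32), with the citrate synthase gene CIT1 at 3.32 ± 0.23. Of the genes of the unfolded protein response of the endoplasmic reticulum 15 of 17 rose and 1 fell (15 and 1 adjusted over the list alone, median 1.93), including ERO1, which drives disulfide formation (4.74 ± 0.25), and the chaperone gene KAR2 (4.35 ± 0.35). Mitochondrial chaperones and proteases had 6 of 11 members higher and 1 lower (6 and 1 adjusted over the list alone, median 1.81). HSP78 was at 7.66 ± 0.33 and HSP60 at 4.19 ± 0.53. Camera gave adjusted p = 2.8e-07, 0.00091, 0.00011 and 0.038 for these 4 lists, in this order, and adjusted p = 0.402 with an estimated correlation for each. Of 32 proteasome genes 19 rose (19 adjusted over the list alone, median 0.68, camera adjusted p = 0.00097, and adjusted p = 0.478 with an estimated correlation), PRE2 by 1.38 ± 0.19. That count was 11 without XH7 30 °C replicate 1 and 8 without replicate 2, and the list's camera call ended with library size as the only scaling (adjusted p = 0.098). PRE1, at 1.00 ± 0.30, lost its call without either XH7 30 °C library or XH7 50 °C replicate 2 (adjusted p up to 0.077, edgeR).

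Of the cytosolic ribosomal protein genes, 134 of 135 fell and RPL15B rose (134 and 1 adjusted over the list alone, median -3.10). RPL9A was at -4.97 ± 0.62 and RPS9B at -4.84 ± 0.64. Of the ribosome biogenesis genes 62 of 63 fell (62 adjusted over the list alone, median -5.07). By camera, adjusted p was 2.6e-21 and 1.6e-18 for them, and adjusted p = 0.478 and 0.402 with an estimated correlation. Amino acid biosynthesis genes fell in 42 of 54 cases and rose in 2 (42 and 2 adjusted over the list alone, median -1.64, camera adjusted p = 1.5e-08), with ILV5 of branched-chain synthesis at -4.07 ± 0.42 and ARO4 of aromatic synthesis at -3.95 ± 0.58. Ergosterol synthesis genes fell in 15 of 24 cases and rose in 3 (15 and 3 adjusted over the list alone, median -0.83, camera adjusted p = 0.0035). ERG13 was at -2.66 ± 0.27 and ERG11, the target of azole drugs, at -1.12 ± 0.24. For both of the last lists camera gave adjusted p = 0.402 with an estimated correlation.

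Genes of sugar use went both ways. Of 17 glycolysis genes 7 rose and none fell (7 adjusted over the list alone), among them the isozyme genes TDH1 (6.74 ± 0.52), HXK1 (5.02 ± 0.25) and PYK2 (3.20 ± 0.42), and GLK1, which overlaps YCL042W (6.27 ± 0.58). The list's camera call (adjusted p = 0.043, adjusted p = 0.848 with an estimated correlation) ended without Z100 50 °C replicate 1, XH7 30 °C replicate 2 or XH7 50 °C replicate 1 (adjusted p = 0.052, 0.101 and 0.169). The count of 7 was 12 without XH7 50 °C replicate 2. In the list of ethanol and acetate metabolism 6 of 18 rose and 7 fell (6 and 7 adjusted over the list alone, camera adjusted p = 0.873), with the aldehyde dehydrogenase genes ALD3 and ALD4 at 6.42 ± 0.56 and 4.34 ± 0.29. The fermentation genes PDC1 and ADH1 had values of 0.02 ± 0.39 (adjusted p = 0.966, edgeR) and 0.94 ± 0.36 (adjusted p = 0.042, edgeR). The ADH1 call ended without 1 of 6 libraries, namely any XH7 library other than 50 °C replicate 2, Z100 30 °C replicate 3, or Z100 50 °C replicate 2 or 3 (adjusted p up to 0.396, edgeR). Hexose transporter and sensor genes rose in 11 of 19 cases and fell in 3 (11 and 3 adjusted over the list alone, camera adjusted p = 0.102), HXT5 by 2.92 ± 0.53, while the transporter genes HXT1 and HXT2 fell (-3.58 ± 0.45 and -4.05 ± 0.35). Of 21 thiamine and vitamin B6 genes 11 fell and 5 rose (11 and 6 adjusted over the list alone, camera adjusted p = 0.229), THI73 by -2.48 ± 0.25. The 11 became 7 without XH7 30 °C replicate 1 or XH7 50 °C replicate 2, and the 5 became 2, 1 and 1 without XH7 30 °C replicate 1, replicate 2 and XH7 50 °C replicate 1.

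In all, 1881 genes rose and 1927 fell in XH7, 3808 of 6015 tested, of which 2885 differed by at least a log2 fold change of 1. Counts of this kind depend on how libraries are scaled, because heat shock moved a large part of the counts: scaling factors were 0.678 to 1.016 at 50 °C and 1.075 to 1.375 at 30 °C. With library size as the only scaling, the median over all genes shifted by -0.547 in XH7 and -0.631 in Z100, -0.129 between strains at 30 °C and -0.220 at 50 °C, and upper-quartile scaling shifted the heat medians by -0.132 and -0.182. Scaling to reference genes shifted the XH7 heat median by 0.124. The share of XH7 heat calls that rose was 49.4%, against 31.4% with library size only. Fold changes of heat are therefore relative to the average gene, and the data hold no measure of total RNA per cell.

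The same comparison in Z100 asked how the evolved strain responds. HSP26 rose from 3.64 ± 1.49 to 38152 ± 10340 CPM (log2 fold change 13.35 ± 0.60), HSP12 from 1.42 ± 0.71 to 4821 ± 487 CPM (11.71 ± 0.58). SSA4 rose by 10.73 ± 0.41, the aggregate-sorting factor gene BTN2 by 9.66 ± 0.55, and the stress genes DDR2 and SPI1 by 8.73 ± 0.48 and 8.59 ± 0.32 (adjusted p between 3.9e-08 and 3.2e-07, edgeR). The deepest falls outside SPO19 (13.8 ± 2.99 CPM to 0, 4 and 0 counts) included HXT2 and HXT3. The hexose transporter gene HXT2 went from 1174 ± 246 to 6.76 ± 0.84 CPM (-7.44 ± 0.34) and HXT3 from 4739 ± 665 to 53.0 ± 4.74 CPM (-6.48 ± 0.41). RRT5, the phosphate transporter gene PHO90 and PDH1 were at -6.53, -5.72 and -5.42.

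Gene groups were tested in Z100 as well. Chaperone and Hsf1 target genes rose in 22 of 24 cases (22 adjusted over the list alone, median 5.89), HSP82 by 7.96 ± 0.36 and HSP104 by 6.33 ± 0.25, and CNS1 and SNL1 again fell. All 29 Msn2/Msn4 genes rose (29 adjusted over the list alone, median 4.98), CTT1 by 4.91 ± 0.25 and SOL4 by 7.99 ± 0.34. So did 16 of 18 trehalose and glycogen genes (16 adjusted over the list alone, median 3.69), TSL1 by 6.16 ± 0.33, TPS1 by 3.65 ± 0.41 and TPS2 by 3.73 ± 0.21. Camera gave adjusted p = 3.8e-11, 5.8e-14 and 1.8e-07, and adjusted p = 0.242, 0.406 and 0.406 with an estimated correlation. Proteasome genes rose in 30 of 32 cases (30 adjusted over the list alone, median 1.09, camera adjusted p = 1.4e-06, and adjusted p = 0.406 with an estimated correlation), PUP2 by 1.87 ± 0.22. The unfolded protein response list had 14 of 17 genes higher and 1 lower (14 and 1 adjusted over the list alone, median 1.42, camera adjusted p = 0.00039, and adjusted p = 0.406 with an estimated correlation). ERO1 was at 6.17 ± 0.22. Respiratory chain genes rose in 25 of 39 cases (25 adjusted over the list alone, median 0.90, camera adjusted p = 0.00073, and adjusted p = 0.557 with an estimated correlation) and the 2 that fell were COX5A and CYC1. For the TCA cycle, 11 of 18 rose and 3 fell (11 and 3 adjusted over the list alone), and the list was not called (adjusted p = 0.138). Mitochondrial chaperones and proteases had 6 of 11 higher and 2 lower (6 and 2 adjusted over the list alone, adjusted p = 0.072). HSP78 was at 7.72 ± 0.27. That list was called without Z100 30 °C replicate 2 (adjusted p = 0.035).

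The genes for ribosomes and for synthesis of amino acids, sterols and vitamins fell in Z100. Ribosomal protein genes fell in 132 of 135 cases and 1 rose (132 and 1 adjusted over the list alone, median -2.94, camera adjusted p = 3.1e-18, and adjusted p = 0.573 with an estimated correlation). RPL3 was at -4.51 ± 0.44. Ribosome biogenesis genes fell in 62 of 63 cases (62 adjusted over the list alone, median -3.62, camera adjusted p = 3.0e-14, and adjusted p = 0.508 with an estimated correlation). ERB1 was at -4.91 ± 0.66 and NOP1 at -4.74 ± 0.53. For amino acid biosynthesis 47 of 54 fell and 1 rose (47 and 1 adjusted over the list alone, median -2.38, camera adjusted p = 3.8e-11, and adjusted p = 0.406 with an estimated correlation). ARG1 was at -4.30 ± 0.32. For ergosterol synthesis 16 of 24 fell and 1 rose (17 and 1 adjusted over the list alone, median -1.07, camera adjusted p = 0.0019, and adjusted p = 0.483 with an estimated correlation). ERG13 was at -3.37 ± 0.23. ERG11 itself, at -0.53 ± 0.19, lost its call without Z100 30 °C replicate 2 or 3 or 50 °C replicate 1 (adjusted p up to 0.107, edgeR). Thiamine and vitamin B6 genes fell in 16 of 21 cases (16 adjusted over the list alone, median -1.65, camera adjusted p = 0.0013, and adjusted p = 0.242 with an estimated correlation), among them SNZ1 (-3.09 ± 0.41). Of the glycolysis list 8 of 17 rose and 1 fell (8 and 1 adjusted over the list alone, adjusted p = 0.149). Of the ethanol and acetate list 5 of 18 rose and 9 fell (5 and 9 adjusted over the list alone, adjusted p = 0.740). Of the hexose transporters 10 of 19 rose and 7 fell (10 and 7 adjusted over the list alone, adjusted p = 0.694). Camera called none of these 3 lists. PDC1, the main pyruvate decarboxylase gene, fell (-1.41 ± 0.32), HXT1 fell (-4.73 ± 0.39), and ADH1 was at 0.32 ± 0.29 (adjusted p = 0.352, edgeR).

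In Z100, 2031 genes rose and 2175 fell with heat, 4206 in all, of which 2993 differed by at least a log2 fold change of 1. The rising share was 48.3%, and 28.1% with library size as the only scaling. Across the 6015 genes the heat log2 fold changes of the strains, which share no library, had a Pearson r of 0.904 and a Spearman rho of 0.890, and genes are not independent replicates. The strains shared 1563 rising genes, where independent lists would share 635, and 1680 falling genes, where they would share 697. There were 14 genes that rose in XH7 and fell in Z100 and 14 that did the reverse. The plot of the heat response of each gene shows both strains.

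**Figure D1:**
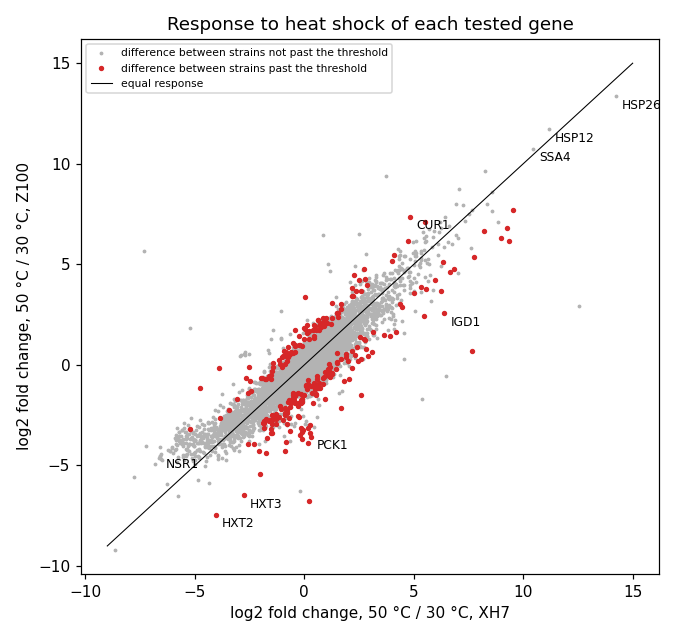
Each point is 1 of 6015 tested genes, with its log2 fold change from 30 °C to 50 °C in XH7 (n = 2 and 2 libraries) on the horizontal axis and in Z100 (n = 3 and 3) on the vertical axis. Points run along the line of equal response (Pearson r 0.904 across genes). Red points are the 257 genes whose response differed between the strains at an adjusted p under 0.05, among them HXT2, HXT3 and PCK1 below the line and CUR1 above it.

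The comparison of Z100 with XH7 at 30 °C asked how the evolved strain differs without heat shock. Z100 had higher levels of genes for storage carbohydrates and stress. IGD1, an inhibitor of glycogen debranching, was at 4.69 ± 0.58 CPM in XH7 and 90.7 ± 32.1 CPM in Z100 (log2 fold change 4.27 ± 0.38, adjusted p = 0.00014, edgeR). TSL1 was at 10.8 ± 0.95 and 166.8 ± 16.4 CPM (3.94 ± 0.36). CTT1 was at 11.5 ± 1.496 and 107.3 ± 8.24 CPM (3.22 ± 0.28). DPI8, the mitochondrial 2-methylisocitrate lyase gene ICL2 and RTC3 were higher by 3.44 ± 0.48, 3.27 ± 0.36 and 3.25 ± 0.26. Lower in Z100 were BSC1 (-3.79 ± 0.35) and its neighbour PRM7 (-3.32 ± 0.39), ANB1, a translation factor gene made when oxygen is scarce (-2.85 ± 0.25), the sorting factor gene CUR1 (-2.58 ± 0.36) and COS4 (-2.66 ± 0.19), which has near-identical copies. SRO9 was lower by a log2 fold change of -2.59 ± 0.87, a call that ended without any 1 of the 5 libraries at 30 °C (adjusted p up to 0.186, edgeR).

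The general stress list had 16 of 29 genes higher and none lower in Z100 (18 adjusted over the list alone, median 1.02), including GAD1 (2.94 ± 0.43) and PGM2 (2.87 ± 0.27). The trehalose and glycogen list had 13 of 18 higher (15 adjusted over the list alone, median 0.95), with the glycogen synthase gene GSY1 at 3.05 ± 0.28, TPS2 at 1.51 ± 0.23 and TPS1 at 2.81 ± 0.47. Mitochondrial groups were higher too: 16 of 18 TCA cycle genes (17 adjusted over the list alone, median 1.51), with SDH1 of succinate dehydrogenase at 2.63 ± 0.35 and CIT1 at 2.14 ± 0.21. So were 27 of 39 respiratory chain genes (31 adjusted over the list alone, median 1.08), with COX5A at 2.13 ± 0.18, and 30 of 67 mitochondrial ribosomal protein genes (36 adjusted over the list alone, median 0.55). RSM7 was at 2.04 ± 0.28. By camera, adjusted p was 2.0e-10, 1.2e-09, 3.8e-13, 1.1e-15 and 1.6e-10 for these 5 lists, and adjusted p = 0.366, 0.366, 0.228, 0.366 and 0.585 with an estimated correlation. The median of each of the first 4 lists stayed between 0.811 and 1.602 under 4 other scalings and without any 1 library. Without XH7 30 °C replicate 1, the stress, trehalose and mitochondrial ribosomal counts were 7, 7 and 13. Without replicate 2, the stress, trehalose, respiratory and mitochondrial ribosomal counts were 7, 6, 16 and 10, and TPS1 lost its call (adjusted p = 0.059, edgeR).

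Iron uptake and nitrogen genes were also higher in Z100 at 30 °C. Of the iron regulon 14 of 20 were higher and FRE1 was lower (16 and 1 adjusted over the list alone, median 1.01, camera adjusted p = 6.3e-08, and adjusted p = 0.366 with an estimated correlation). Among them were the high-affinity uptake pair FET3 (2.95 ± 0.27) and FTR1 (2.72 ± 0.34). Of the genes repressed by good nitrogen sources 14 of 22 were higher and DAL5 was lower (16 and 1 adjusted over the list alone, median 1.10, camera adjusted p = 2.8e-06, and adjusted p = 0.366 with an estimated correlation). Among them were the proline permease gene PUT4 (2.75 ± 0.41) and the ammonium permease gene MEP3 (1.37 ± 0.20). Of the methionine and sulphur genes 12 of 24 were higher and 1 lower (17 and 2 adjusted over the list alone, median 0.86, camera adjusted p = 0.00014, and adjusted p = 0.585 with an estimated correlation). MMP1 was at 1.43 ± 0.24 (adjusted p up to 0.071 without XH7 30 °C replicate 2, edgeR). Without XH7 30 °C replicate 1 the counts of higher iron, nitrogen and methionine genes were 9, 4 and 2, and without replicate 2 they were 8, 3 and 0. Without Z100 30 °C replicate 3 the nitrogen count was 8 and the methionine count 7, which was also the methionine count without Z100 30 °C replicate 1.

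Ribosome biogenesis genes were lower in Z100 at 30 °C in 18 of 63 cases and higher in none (18 adjusted over the list alone, median -0.90, camera adjusted p = 2.8e-06, and adjusted p = 0.711 with an estimated correlation). KRR1 was at -2.08 ± 0.59 and NOP14 at -1.59 ± 0.50. Both genes lost their calls without any 1 of the 30 °C libraries (adjusted p up to 0.141 and 0.225, edgeR). That list's count was 5 without any 1 Z100 30 °C library, 2 and 0 without XH7 30 °C replicates 1 and 2, and 38 without Z100 50 °C replicate 2. The cytosolic ribosomal proteins themselves had 4 of 135 genes lower and 1 higher (1 and 1 adjusted over the list alone, median -0.25, adjusted p = 0.305, not called), RPL9B by -1.39 ± 0.21 and RPS14B by 1.56 ± 0.25. The count of 4 ran from 1, without any 1 library at 30 °C, to 16 without XH7 50 °C replicate 1. It was 7 without Z100 50 °C replicate 2, 2 without Z100 50 °C replicate 3 and 11 without XH7 50 °C replicate 2. The unfolded protein response list had 8 of 17 genes lower and 1 higher (10 and 1 adjusted over the list alone, median -0.60, camera adjusted p = 0.0042, and adjusted p = 0.585 with an estimated correlation). SIL1 was at -1.37 ± 0.18 and ERO1 at -1.20 ± 0.19. That count was 5, 4 and 3 without Z100 30 °C replicate 3 and XH7 30 °C replicates 1 and 2.

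Chaperone genes did not move together at 30 °C. HSP42 was higher in Z100 by 2.07 ± 0.23 and HSP104 by 1.05 ± 0.23, while CUR1 and 5 others of the 24 were lower and 15 were not called (4 higher and 6 lower adjusted over the list alone, median -0.27, camera adjusted p = 0.298). The counts of 3 higher and 6 lower became 1 and 2 without XH7 30 °C replicate 1 and 1 and 1 without replicate 2. HSP12 was at 2.12 ± 0.50 and, as HSP104, lost its call without either XH7 30 °C library (adjusted p up to 0.103 and 0.113, edgeR). HSP26 had a value of 1.30 ± 0.44 (adjusted p = 0.051, edgeR) and SSA4 of 0.21 ± 0.30 (adjusted p = 0.614, edgeR). Ergosterol genes were lower in 8 of 24 cases and higher in 2 (8 and 2 adjusted over the list alone, median -0.32, camera adjusted p = 0.112). ERG11 was at -1.28 ± 0.21. The 8 became 4, 4, 3, 1 and 1 without Z100 30 °C replicates 1, 2 and 3 and XH7 30 °C replicates 1 and 2. Camera called the list without Z100 30 °C replicate 2 or XH7 30 °C replicate 2 (adjusted p = 0.039 and 0.036). In the ethanol and acetate list 4 of 18 were higher and 2 lower (7 and 2 adjusted over the list alone, median 0.63, camera adjusted p = 0.020, adjusted p = 0.636 with an estimated correlation, and adjusted p = 0.056 without Z100 30 °C replicate 2). ALD4 was at 2.48 ± 0.25. Its count of 4 was 2, 1, 7 and 8 without XH7 30 °C replicates 1 and 2 and XH7 50 °C replicates 1 and 2. PDC1, ADH1 and HXT1 had values of 0.61 ± 0.36, 0.57 ± 0.33 and 0.59 ± 0.38, none called (adjusted p of at least 0.212, edgeR).

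In total 861 genes were higher and 848 lower in Z100 at 30 °C, 1709 of 6015, of which 804 differed by at least a log2 fold change of 1. The count was 292 without XH7 30 °C replicate 2, 552 without replicate 1, and 1139, 1060 and 924 without Z100 30 °C replicates 1, 2 and 3. It was 3155 in a fit of the 30 °C groups alone. The share of higher genes was 50.4%, against 42.6% with scaling to reference genes and 60.6% without the 1% most abundant genes. The plot of gene list medians sets these differences beside the heat responses.

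**Figure D2:**
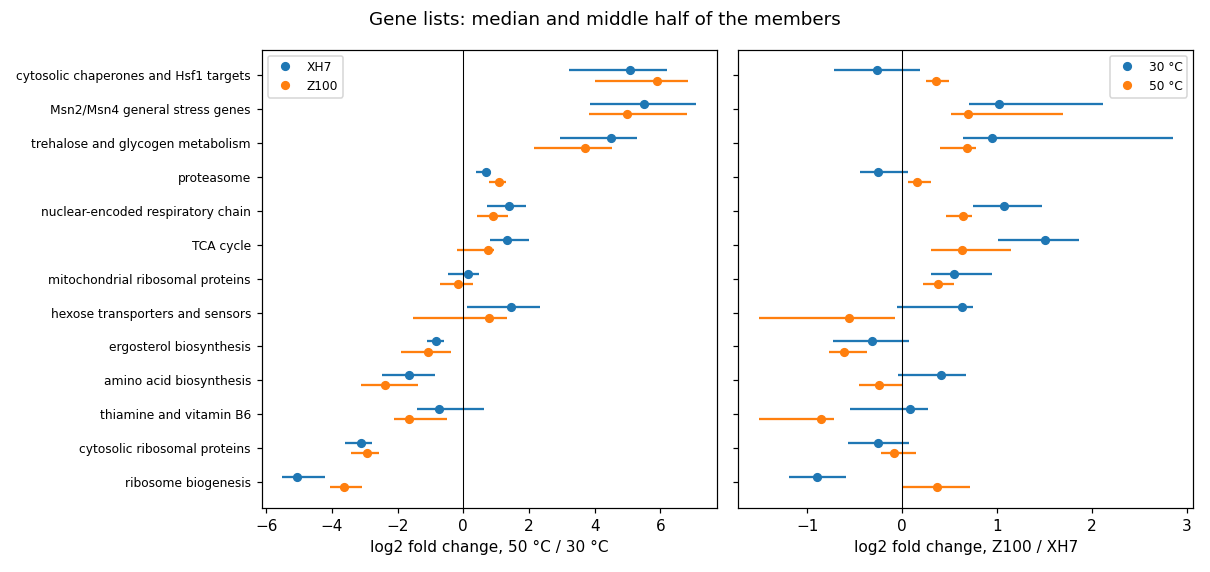
Points are the median log2 fold change of the tested genes of 13 gene lists and lines span the 25th to the 75th percentile of their members, for heat shock against 30 °C in each strain on the left and for Z100 against XH7 at each temperature on the right. Ribosome biogenesis had medians of -5.07 and -3.62 for heat in XH7 and Z100, and the TCA cycle had medians of 1.51 and 0.63 for the strains at 30 °C and 50 °C.

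The comparison of Z100 with XH7 at 50 °C asked how the strains differ after heat shock. HSP12 was higher in Z100, at 4821 ± 487 CPM against 756 ± 314 CPM (log2 fold change 2.67 ± 0.46, adjusted p = 0.012, edgeR). So were DDR2 (2.68 ± 0.42), ECM13 (2.26 ± 0.28), RTN2 (2.19 ± 0.26), the metal reductase gene FRE2 (2.05 ± 0.31) and CTT1 (1.87 ± 0.26). Lower in Z100 were PCK1, the gluconeogenic enzyme gene, at 1.96 ± 0.29 CPM against 22.5 ± 14.99 CPM (-3.51 ± 0.37), the hexose transporter genes HXT3 (-3.03 ± 0.37), HXT4 (-2.26 ± 0.39) and HXT2 (-2.22 ± 0.28). COS4, which has near-identical copies (-2.90 ± 0.18), the cell wall mannoprotein gene TIR1 (-2.51 ± 0.38) and PRM7 (-2.28 ± 0.39) were lower too. FMP45 had the largest rise, 4.05 ± 0.94, but 1 of its 3 Z100 libraries was at 773 CPM and the others at 90.2 and 101.8 CPM. Its call ended without Z100 30 °C replicate 1 or 3 or any 1 XH7 library (adjusted p up to 0.090, edgeR). In a fit of the 50 °C groups alone COS4 and TIR1 were called, and the other called genes of this paragraph were not (adjusted p from 0.063 for HSP12 to 0.193 for FMP45, edgeR). The major heat-induced chaperones were not called: HSP26, SSA4 and HSP104 had values of 0.43 ± 0.41, 0.48 ± 0.30 and 0.37 ± 0.22, and TPS1 and TPS2 of 1.13 ± 0.43 and 0.70 ± 0.22 (adjusted p between 0.076 and 0.544, edgeR). PDC1, ADH1, ERG11 and HXT1 were not called either, at -0.82 ± 0.35, -0.05 ± 0.32, -0.69 ± 0.21 and -0.56 ± 0.37.

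Member counts and p-values at 50 °C rest on 1 spread per gene over all groups, drawn in part from the tighter 30 °C libraries. Camera called 15 of 40 lists. Those not described include amino acid biosynthesis and meiosis, called lower, and the proteasome and antioxidant genes, called higher. The unfolded protein response list was lower here too, with 4 of 17 genes lower (7 adjusted over the list alone, median -0.53, camera adjusted p = 0.010, and adjusted p = 0.491 with an estimated correlation). Of the general stress genes 10 of 29 were higher in Z100 at 50 °C and none lower (17 adjusted over the list alone, median 0.69). Of the TCA cycle 9 of 18 were higher (10 adjusted over the list alone, median 0.63). FUM1 was at 1.67 ± 0.26 and CIT1 at 1.26 ± 0.20. Of the respiratory chain 12 of 39 were higher (22 adjusted over the list alone, median 0.65). COX4 was at 1.28 ± 0.23 and ATP17 at 1.13 ± 0.17. Camera gave adjusted p = 4.9e-11, 1.4e-07 and 2.0e-12, and adjusted p = 0.317, 0.279 and 0.286 with an estimated correlation. The stress count was 6 without Z100 50 °C replicate 1 or 3 and 5 without XH7 50 °C replicate 2 or either XH7 30 °C library. The TCA count was 4 without Z100 50 °C replicate 3. The respiratory count was 2 without Z100 50 °C replicate 3, 5 without XH7 50 °C replicate 1 or either XH7 30 °C library, 7 without Z100 30 °C replicate 1 or Z100 50 °C replicate 1, 6 without Z100 30 °C replicate 3, and 22 without XH7 50 °C replicate 2. Of 24 chaperone genes SSE2 (1.03 ± 0.18) and APJ1 (0.93 ± 0.20) were higher (2 adjusted over the list alone, median 0.36, camera adjusted p = 9.3e-05, and adjusted p = 0.411 with an estimated correlation). The APJ1 call ended without any 1 of 5 libraries, namely Z100 30 °C replicate 3, Z100 50 °C replicates 1 and 3 and both XH7 30 °C libraries (adjusted p up to 0.063, edgeR). In the trehalose and glycogen list 2 of 18 were higher (6 adjusted over the list alone, median 0.69, camera adjusted p = 4.9e-05, and adjusted p = 0.483 with an estimated correlation). GSY2 was at 1.21 ± 0.19. The 2 became 1 without any 1 library other than Z100 30 °C replicate 2 and XH7 50 °C replicate 1. Mitochondrial ribosomal proteins had 6 of 67 higher and 1 lower (7 and 1 adjusted over the list alone, median 0.38, camera adjusted p = 2.4e-07, and adjusted p = 0.491 with an estimated correlation). That 6 was 0 without Z100 50 °C replicate 3 or either XH7 30 °C library, 1 without Z100 30 °C replicate 3 or XH7 50 °C replicate 1, and 17 without XH7 50 °C replicate 2.

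Thiamine and vitamin B6 genes were lower in Z100 at 50 °C in 8 of 21 cases and higher in none (12 adjusted over the list alone, median -0.86). THI73 was at -1.57 ± 0.22 and SNZ3, which has a near-identical copy in SNZ2, at -1.58 ± 0.30. This was the 1 list of 40 in any comparison whose camera call (adjusted p = 4.6e-08) held with an estimated correlation (adjusted p = 0.026 with an estimated correlation). That setting called no list for heat in either strain, not even cytosolic ribosomal proteins in XH7, of which 134 of 135 fell. A pass or a failure there therefore says little about how the lists rank. SNZ2 and SNZ3 also count as separate members of the thiamine list. Its count was 5 without Z100 30 °C replicate 1 or 3, 4 without Z100 50 °C replicate 3 and 3 without either XH7 30 °C library. PAU family genes, a set of near-identical seripauperin genes whose reads cannot be assigned with certainty, were lower in 6 of 19 cases (6 adjusted over the list alone, median -1.22, camera adjusted p = 1.5e-07, and adjusted p = 0.148 with an estimated correlation). PAU11 was at -2.04 ± 0.35. Their count was 1 without Z100 50 °C replicate 3 or either XH7 30 °C library, 2 without Z100 50 °C replicate 2 or XH7 50 °C replicate 1, and 3 without Z100 30 °C replicate 3. Ergosterol genes were lower in 5 of 24 cases (12 adjusted over the list alone, median -0.61, camera adjusted p = 6.5e-07, and adjusted p = 0.286 with an estimated correlation). ERG3 was at -1.06 ± 0.18. That count was 1 without Z100 50 °C replicate 3, 2 without Z100 50 °C replicate 1 or either XH7 30 °C library and 3 without Z100 30 °C replicate 1 or 3. Hexose transporters and sensors had 5 of 19 lower and HXT6, which has a near-identical copy in HXT7, higher (7 and 3 adjusted over the list alone, median -0.56, camera adjusted p = 0.010, and adjusted p = 0.483 with an estimated correlation). The 5 became 3 without Z100 50 °C replicate 3 or XH7 50 °C replicate 1, and without the latter the list was not called (adjusted p = 0.093).

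None of the 63 ribosome biogenesis genes was called at 50 °C by edgeR (3 at an unadjusted p under 0.05; 0 adjusted over the list alone, median 0.37, camera adjusted p = 0.345). NSR1 was at 1.499 ± 0.53 (adjusted p = 0.107, edgeR). The direction of that list rested on single heat-shocked libraries: without Z100 50 °C replicate 2 its median was -0.32 and called lower (adjusted p = 0.0087). Without Z100 50 °C replicate 1 or 3 or XH7 50 °C replicate 2 it was 0.54, 0.60 or 0.79 and called higher (adjusted p = 0.021, 0.00084 and 0.034).

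In total 242 genes were higher and 297 lower in Z100 at 50 °C, 539 of 6015, of which 256 differed by at least a log2 fold change of 1. The share of higher genes was 44.9%, against 17.7% with library size as the only scaling, 31.7% with scaling to reference genes, 33.9% with upper-quartile scaling and 55.1% by DESeq2, which called 1061. The model gave each gene 1 spread over all groups, so the tighter 30 °C libraries lowered the error at 50 °C. With the replicate number as a block at 50 °C only, a fit chosen after the data were seen, the count was 1497. In a fit of the 50 °C groups alone the count was 4. Without 1 library it was 146 (Z100 50 °C replicate 3), 186 and 188 (XH7 30 °C replicates 2 and 1), 244 and 304 (Z100 30 °C replicates 3 and 1), 318 (Z100 50 °C replicate 1) and 328 (XH7 50 °C replicate 1). Across genes the strain differences at 30 °C and 50 °C had a Pearson r of 0.335, and 114 higher and 130 lower genes were called at both temperatures, where independent lists would share 34.6 and 41.9. Another 12 and 15 of the genes higher and lower at 30 °C were called in the opposite direction at 50 °C.

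The test of the difference in heat response between the strains asked which genes Z100 regulates otherwise under heat. PCK1 kept 18.3 ± 1.79 and 22.5 ± 14.99 CPM at 30 °C and 50 °C in XH7 but went from 23.5 ± 2.68 to 1.96 ± 0.29 CPM in Z100 (difference in log2 fold change -3.87 ± 0.52, adjusted p = 0.0079, edgeR). HXT3 (-3.73 ± 0.53) and HXT2 (-3.39 ± 0.41) fell further in Z100. PDH1, a gene of propionate metabolism, went from 19.4 ± 0.99 to 4.84 ± 0.55 CPM in XH7 and from 106.2 ± 21.2 to 2.48 ± 0.38 CPM in Z100 (-3.42 ± 0.30, adjusted p = 0.0013, edgeR). IGD1 (-3.84 ± 0.46) and ICL2 (-3.84 ± 0.46) were already high in Z100 at 30 °C. CUR1 responded more strongly in Z100 (2.52 ± 0.51), from a lower start to a like end, 620 ± 258 CPM in XH7 and 596 ± 120 CPM in Z100. KEL3 (2.43 ± 0.32), IPI3 (2.06 ± 0.47), ANB1 (2.01 ± 0.35), SNM1 (1.88 ± 0.27) and LRP1 (1.87 ± 0.40) also had a higher response in Z100. The plot of single genes per library shows several of these. None of the anchor genes was called: HSP104, SSA4, HSP26, HSP12, CTT1, TPS1, TPS2, PDC1, ADH1, ERG11 and HXT1 had values from -1.68 to 0.58 (adjusted p of at least 0.055, edgeR).

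In all, 98 genes had a higher and 159 a lower response in Z100, 257 of 6015, and DESeq2 called 834. Of the 257, 212 also differed between the strains at 30 °C, 211 of them in the opposite direction, and 79 differed at 50 °C. The 30 °C libraries enter both values with opposite sign, so part of that opposition arises from sampling error alone. The result rests on few libraries: the count was 2 without XH7 30 °C replicate 2 and 22 without XH7 30 °C replicate 1. It was 57 and 114 without Z100 30 °C replicates 3 and 1, 87 without Z100 50 °C replicate 3, 137 without XH7 50 °C replicate 1, 432 without Z100 50 °C replicate 1 and 1065 without XH7 50 °C replicate 2. Of 44 named genes called here, PDH1 alone was called without any 1 library and the other 43 lost their calls without XH7 30 °C replicate 2. The share of higher responses was 38.1%, and 11.5% with library size as the only scaling.

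**Figure D3:**
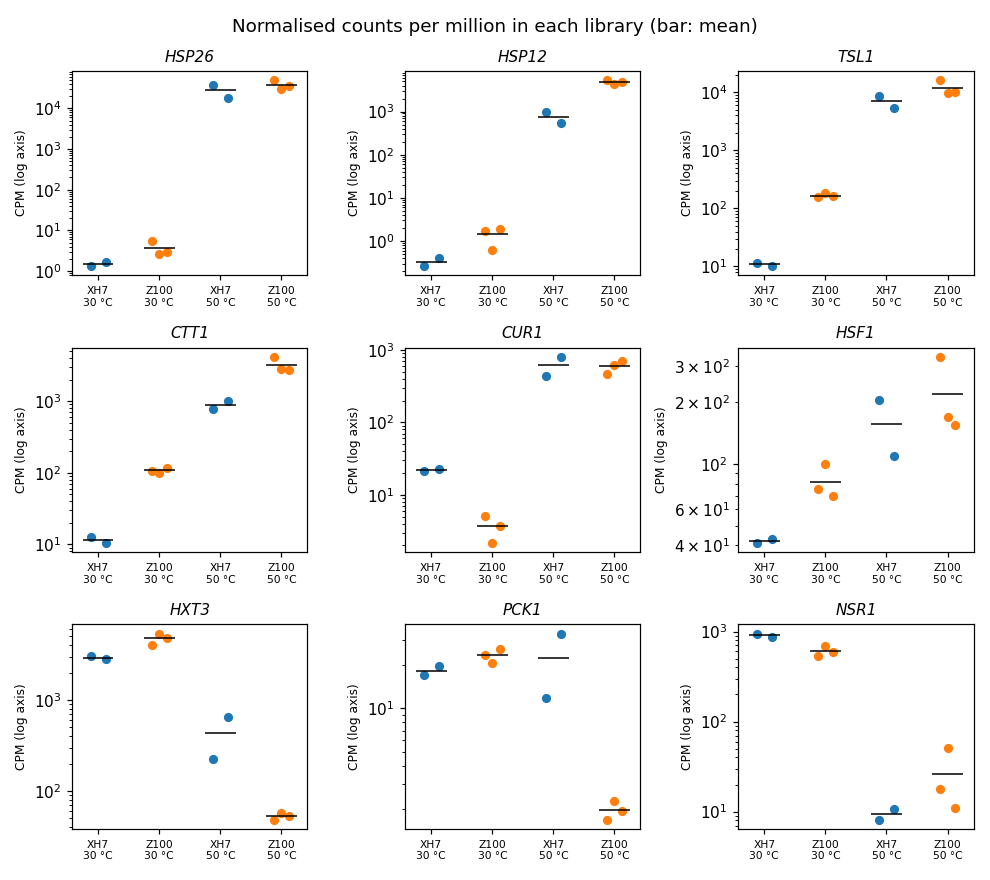
Normalised CPM (log axis) of 9 genes in each of the 10 libraries, XH7 in blue and Z100 in orange, with a bar at each group's mean. HSP26 lay between 28256 and 38152 CPM on average after heat shock in both strains, while PCK1 fell to 1.96 CPM in Z100 and stayed at 22.5 CPM in XH7.

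Camera called 19 of 40 lists here, 3 higher and 16 lower, none of them with an estimated correlation. Of these 10 are described, and those left out include the proteasome, called higher, and the methionine, thiamine and PAU lists, called lower. Lower heat responses in Z100 were called for hexose transporters (4 of 19 lower, 8 lower and 1 higher adjusted over the list alone, median -1.15). HXT4 was at -3.01 ± 0.57. Nitrogen genes followed (6 of 22 lower, 9 adjusted over the list alone, median -1.03), with MEP3 at -2.26 ± 0.27. Gluconeogenesis and glyoxylate genes were lower in 5 of 13 cases (6 lower and 1 higher adjusted over the list alone, median -1.11), with the malate synthase gene MLS1 at -2.30 ± 0.36. The iron regulon was lower in 5 of 20 cases (11 adjusted over the list alone, median -0.77), with the siderophore transporter gene SIT1 at -2.60 ± 0.37. Their adjusted p-values were 0.00011, 6.8e-07, 0.0020 and 6.8e-07, with adjusted p = 0.301, 0.281, 0.473 and 0.281 with an estimated correlation. The same held for the TCA cycle (3 of 18, 12 adjusted over the list alone, median -0.76) and the respiratory chain (4 of 39, 9 adjusted over the list alone, median -0.52). COX5A was at -1.65 ± 0.24. It also held for trehalose and glycogen genes (5 of 18, 5 adjusted over the list alone, median -0.68) and amino acid biosynthesis (10 of 54, 14 adjusted over the list alone, median -0.66). TSL1 was at -3.18 ± 0.43 and ARG1 at -2.22 ± 0.44. Their adjusted p-values were 3.2e-06, 0.00011, 0.00011 and 3.8e-06, with adjusted p = 0.281, 0.477, 0.477 and 0.477 with an estimated correlation. In the order given, the 8 counts were 0 in each list without XH7 30 °C replicate 2, and 1, 1, 0, 0, 0, 0, 1 and 0 without replicate 1. They were 2, 1, 3, 2, 0, 1, 3 and 0 without Z100 30 °C replicate 3 and 2, 3, 3, 2, 0, 1, 3 and 0 without Z100 50 °C replicate 3. Without XH7 50 °C replicate 2, hexose transporters, nitrogen, iron, TCA cycle and respiratory chain genes had 9, 10, 11, 6 and 7, and the respiratory chain list was not called (adjusted p = 0.074). Iron, TCA cycle, respiratory chain and amino acid genes had 3, 1, 2 and 2 without Z100 30 °C replicate 1, and iron, TCA cycle and amino acid genes had 3, 1 and 5 without XH7 50 °C replicate 1. The TCA cycle and respiratory chain counts were 1 and 2 without Z100 30 °C replicate 2 or Z100 50 °C replicate 2, and the TCA cycle count was 5 without Z100 50 °C replicate 1.

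Among the higher heat responses called in Z100 were those of chaperone genes (3 of 24 higher and HSP42 lower, 5 and 1 adjusted over the list alone, median 0.73, camera adjusted p = 0.00011, and adjusted p = 0.367 with an estimated correlation). YDJ1 was at 1.25 ± 0.25 and SSE1 at 1.24 ± 0.26. The ribosome biogenesis list, whose fall was less deep in Z100, was also called higher (median 1.24, camera adjusted p = 3.1e-07, and adjusted p = 0.653 with an estimated correlation). Without Z100 50 °C replicate 2 that median was 0.632 (adjusted p = 3.2e-06). No single ribosome biogenesis gene of 63 passed in edgeR (24 at an unadjusted p under 0.05; 0 adjusted over the list alone); the smallest p was that of RRP12, at 1.60 ± 0.40 (adjusted p = 0.054, edgeR). That count was 8 without XH7 50 °C replicate 2, 4, 2 and 3 without Z100 50 °C replicates 1, 2 and 3, and 1 without Z100 30 °C replicate 2. The 3 chaperone calls were lost without either XH7 30 °C library or Z100 30 °C or 50 °C replicate 3, and 1 was left without Z100 30 °C replicate 1. The Msn2/Msn4 list was not called (1 of 29 higher and 4 lower, 1 and 8 adjusted over the list alone, median 0.01, adjusted p = 0.139), with a mean of -0.27 opposite in sign to its median. It was called lower without Z100 50 °C replicate 1 or XH7 50 °C replicate 2 (adjusted p = 0.033 for both).

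Because gains and losses of chromosomes are common in evolved yeast, strain differences were compared by chromosome on the R64 genome. Genes of chromosome III were lower in Z100 at both temperatures. The median of its 166 tested genes lay -0.495 from the genome-wide median at 30 °C and -0.600 at 50 °C on the log2 scale, or 0.71-fold and 0.66-fold. Of these genes 115 and 157 lay below it at the 2 temperatures, 71 and 40 were called lower, and 7 and 0 were called higher. By camera, adjusted p was 7.0e-06 at 30 °C (adjusted p = 0.077 with an estimated correlation) and 6.7e-19 at 50 °C (adjusted p = 0.0034 with an estimated correlation). Of its genes, KCC4, a septin-associated kinase gene (79162 to 82275), was at -2.56 ± 0.21 at 30 °C and GIT1, a glycerophosphoinositol transporter gene (297049 to 298605), at -2.21 ± 0.31 at 50 °C. HSP30 (156109 to 157107) was among the 7 called higher at 30 °C, with 2.62 ± 0.22. Leaving out any 1 library kept the chromosome's relative median between -0.495 and -0.462 at 30 °C and between -0.670 and -0.485 at 50 °C.

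Genes of chromosome VII were higher in Z100 by 0.162 relative to the genome at 30 °C (535 genes, camera adjusted p = 0.326) and by 0.188 at 50 °C (camera adjusted p = 0.0025, and adjusted p = 0.059 with an estimated correlation). The call at 50 °C ended without XH7 50 °C replicate 1 (0.158, adjusted p = 0.0735). Runs of windows of 25 genes were sought in which Z100 was higher by more than 0.3 relative to the genome at both temperatures. Their ends depend on that limit, and short runs were left out. The longest lay on the left arm of chromosome VII, from LYS5 to TYW3 (215278 to 406597, 97 genes). Its relative medians were 0.498 and 0.484, or 1.41-fold and 1.40-fold. Of the 97 genes 76 and 87 lay above the genome median at 30 °C and 50 °C, which follows in part from choosing the run for its higher medians. A second run lay from MTC3 to MND1 (73340 to 157285), with relative medians of 0.723 and 0.545, and a run on chromosome XII lay from YLR159C-A, which has near-identical copies, to APS1 (485711 to 501049), with 0.561 and 0.344. The relative medians of the 14 other chromosomes lay between -0.083 and 0.165 at 30 °C and between -0.059 and 0.022 at 50 °C, with no camera call. Among called genes of chromosome VII at 50 °C, CTT1 was higher (1.87 ± 0.26) and PAU11, which has near-identical copies, and COS6 were lower (-2.04 ± 0.35 and -1.99 ± 0.25). In the difference in heat response no chromosome was called, III being at -0.107 and VII at 0.038.

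**Figure D4:**
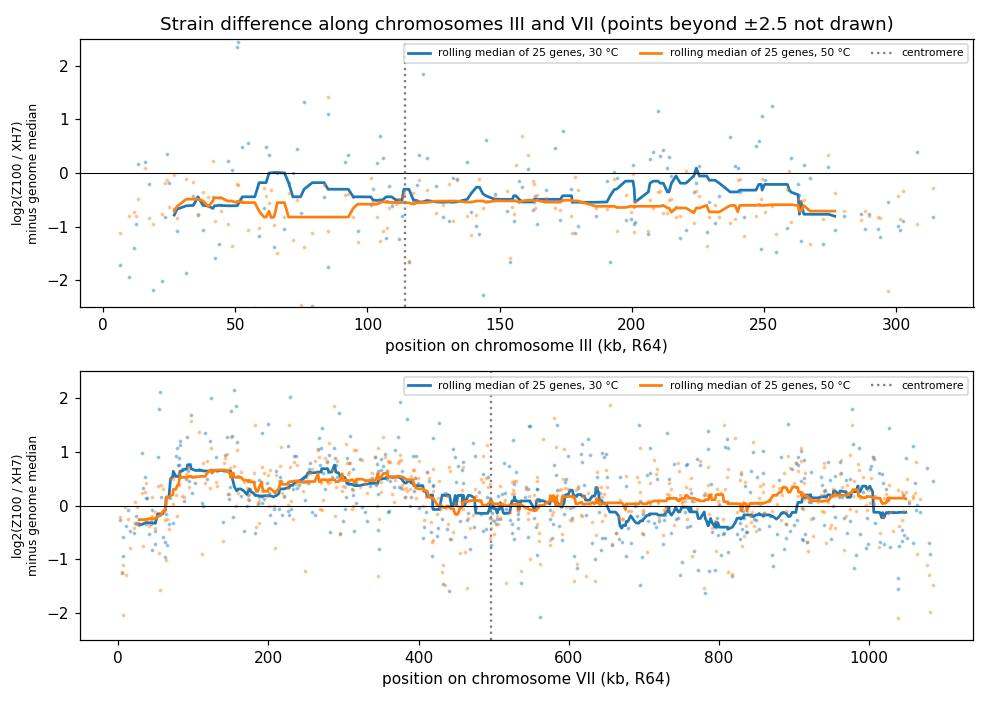
Log2 ratio of Z100 to XH7 for each tested gene (points) minus the genome median, at 30 °C (blue) and 50 °C (orange), against position in kb on chromosomes III and VII, with a rolling median of 25 genes as lines and the centromere dotted. The lines lie below 0 along most of chromosome III and above 0 on the left arm of chromosome VII between 215278 and 406597, at both temperatures.

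No gene had at most 3 counts in every library of 1 strain and at least 50 in every library of the other, and the count was also 0 with limits of 0 and 20 counts and without any 1 library. No gene loss was detectable at this depth by that rule.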

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

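The tests of single libraries in the first 2 patterns, of scaling in the second, and of growth state and copy number in the first were chosen after the results were seen. The tests of GC content, growth stage and the third pattern, and the splits, were set before their own values were seen. The patterns that all these tests address came from these data.

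The heat response differed between the strains for 257 genes in the edgeR test of the difference itself. Higher in Z100 were the responses of CUR1 (2.52), KEL3 (2.43), IPI3 (2.06), ANB1 (2.01), SNM1 (1.88) and LRP1 (1.87), as differences in log2 fold change. Lower were those of PCK1 (-3.87), IGD1 (-3.84), ICL2 (-3.84), HXT3 (-3.73), PDH1 (-3.42) and HXT2 (-3.39). Among the 19 lists that camera called for this difference, 10 were described, namely chaperones (median 0.73), ribosome biogenesis (1.24, and 0.632 without Z100 50 °C replicate 2), trehalose and glycogen (-0.68), hexose transporters (-1.15), the TCA cycle (-0.76), the respiratory chain (-0.52), amino acid biosynthesis (-0.66), the iron regulon (-0.77), nitrogen genes (-1.03) and gluconeogenesis (-1.11). None of the 19 was called with an estimated correlation, and the 257 became 2 without XH7 30 °C replicate 2 and 22 without XH7 30 °C replicate 1.

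The first pattern is that genes of chromosome III were lower and those of a left-arm segment of chromosome VII higher in Z100. GC content and gene length do not account for it: the region median nearest to 0 was still 0.506 in size after their trend was removed. For chromosome III a single library does not account for it either, as its median stayed at -0.462 or further from 0 without any 1 library. The segment kept at least 0.464, but its genes were chosen with all libraries, so this decides little about a single library. A growth or stress state stays open for both regions: their medians moved with heat by at most -0.068 for chromosome III and -0.207 for the segment, relative to the genome, but single genes went both ways and heat does not stand for other states. A difference in gene copy number may underlie chromosome III, whose medians at 30 °C and 50 °C differed by 0.105 and whose libraries separated by strain at both temperatures; this is a hypothesis found and tested on the same data. For the segment, chosen for being higher at both temperatures, the like difference of 0.014 follows from that choice and copy number stays open.

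The second pattern is that stress, storage carbohydrate and respiratory genes were higher and ribosome biogenesis genes lower in Z100 at 30 °C. The list medians stayed at least 0.811 from 0 under 4 other scalings. These moved all genes by at most -0.129, so no median could have turned and that test decides nothing. Scaling as the whole cause is argued against by the opposite signs, since 1 shift of all genes cannot raise 4 lists and lower ribosome biogenesis. A single library is argued against by medians that kept at least 0.917 of their size. Cultures sampled at another growth stage or glucose level cannot be told apart from a lasting difference between the strains, because the design holds 1 condition per strain at 30 °C. The glucose-repressed gluconeogenesis and glyoxylate genes had a median of 0.596 in Z100 against XH7, with 4 of 13 higher and 1 lower (camera adjusted p = 0.084). This median lay beyond the limit set in advance for another growth stage or glucose level. A lasting difference between the strains could give the same value, so it does not decide between them.

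The third pattern is that strain differences at 30 °C were smaller after heat shock: the 861 genes higher at 30 °C had a median log2 difference of 1.04 there and 0.32 at 50 °C, and the 848 lower ones -0.90 and -0.32. Choosing genes by their 30 °C value makes some shrinkage certain, so the slope across all genes, corrected for error at 30 °C, was used; it was 0.274. It was 0.11 without XH7 50 °C replicate 2, 0.17 without Z100 50 °C replicate 1 and at most 0.434, without XH7 50 °C replicate 1, below the 0.8 set in advance for sampling error as the whole cause. Other scalings gave at most 0.29, which decides nothing about scaling, since rescaling shifts all genes alike. A low slope does not by itself show that strain differences shrank as a whole, since a weak correlation across genes also lowers it. That correlation was a Pearson r of 0.335. The SD over genes of the strain differences, sampling error included, was 0.845 at 30 °C and 0.597 at 50 °C. No biological explanation was tested.

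Of the 10 splits of the 6 Z100 libraries into 3 and 3, too few for a share under 0.05, 1, the real one, called as many as 4206 genes, and the highest other called 0. For lists, the real split called 15, and 9 of the 10 splits called as many, with 22 as the highest other. The camera test with the preset correlation of 0.01 thus called lists in splits that mix the temperatures. Each group of 3 in those splits held more libraries of 1 temperature than of the other. Part of the heat difference therefore stayed between the groups, and the rest raised the spread within them. For this reason the splits cannot tell whether camera calls too many lists, and the 0 genes called in the other splits decide nothing either.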

How the results depend on the processing

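The fits with the replicate block at 50 °C only, without both libraries numbered 1 at 50 °C and without chromosome III and the left arm of chromosome VII were chosen after the data were seen. Of 9907 alternative values of 371 named gene results, 9081 kept direction and side of the threshold, 777 were no longer past it, 49 came past it and 0 turned. Of 1140 values of 76 list results, 1059 kept both, 70 were no longer past it, 10 came past it and 1 turned: ribosome biogenesis at 50 °C, -0.32 without Z100 50 °C replicate 2 (-0.32 to 0.79 over left-out libraries, and 0.37 with all). Against a log2 fold change of 1 (glmTreat), calls were 2047 and 2271 for heat in XH7 and Z100, 115 and 5 for the strains at 30 °C and 50 °C and 23 for the interaction; by size alone (at least 1) they were 804 and 256 for the strains. Fits of the compared groups alone gave 3155 at 30 °C and 4 at 50 °C. DESeq2 gave 1061 at 50 °C and 834 for the interaction. The replicate block gave 240 at 50 °C and 152 for the interaction, the block within strain 18 for the interaction, and the block at 50 °C only 1497 at 50 °C; the block left the other counts within 1.5 times. The numbers were not treated as pairing the samples: correlations of deviations between same-numbered libraries were 0.635 and 0.529 between strains at 50 °C, and not all others passed 0.1. Without both libraries numbered 1 at 50 °C the interaction had 461 calls. The cause of these shifts was not tested. With an estimated correlation, camera called 0, 0, 0, 1 and 0 lists in the 5 comparisons, against 18, 15, 15, 15 and 19. The heat correlation across genes was 0.922 with the filter at 5 CPM.

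Without 1 library, calls ranged from 3053 to 3940 (heat in XH7), 3837 to 4415 (heat in Z100), 292 to 2223 (strains at 30 °C), 146 to 607 (strains at 50 °C) and 2 to 1065 (interaction). Chromosome III ranged from -0.495 to -0.462 at 30 °C and -0.670 to -0.485 at 50 °C, chromosome VII from 0.143 to 0.169 and 0.158 to 0.218, and the heat correlation from 0.878 to 0.917. Of the named calls, 87 of 90 (heat in XH7), 88 of 89 (heat in Z100), 43 of 70 (30 °C), 25 of 47 (50 °C) and 1 of 44 (interaction) held without any 1 library. Transcript counts were not run, since they equal the gene counts, and tests of annotation terms were not run, since the tables hold no terms. At this depth the floor of 3 counts lies at or below 0.058 CPM. In simulated data, 2-fold changes were recovered in 4% (interaction) to 58% (heat in Z100) of cases. Few genes changed there and each gene had 1 spread over all groups, so rates in the real comparisons may differ.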

Other observations

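HSF1 and its place on chromosome VII were chosen for this part after the values were seen.

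Heat moved further groups in both strains. Regulators of heat and stress rose in 17 of 25 cases in XH7 and 19 in Z100, and 4 fell in each (17 and 4, and 19 and 4, adjusted over the list alone; medians 1.40 and 1.30): CIN5 rose by 5.07 ± 0.59 and 5.42 ± 0.49, and RPN4, which activates proteasome genes, by 3.53 ± 0.21 and 3.70 ± 0.18. Antioxidant genes rose in 20 and 19 of 30 cases and fell in 2 and 3 (21 and 3, and 19 and 3, adjusted over the list alone; medians 1.32 and 1.19), with OYE3 at 4.34 ± 0.73 and 4.70 ± 0.61. Autophagy genes rose in 15 of 24 cases in each strain and fell in 2 and 3 (15 and 2, and 15 and 3, adjusted over the list alone; medians 1.22 and 0.98), with ATG8 at 3.35 ± 0.33 and 2.75 ± 0.26. Camera adjusted p-values in XH7 and Z100 were 0.0061 and 0.0013 for regulators, 0.00033 and 0.0013 for antioxidant genes and 0.0061 and 0.014 for autophagy, each with an adjusted p of at least 0.402 with an estimated correlation.

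Genes of DNA replication and S phase fell with heat in 17 of 25 cases in XH7 and 16 in Z100, and rose in 2 and 4 (17 and 2, and 17 and 4, adjusted over the list alone; medians -1.20 and -0.80). POL1, of the polymerase that starts DNA strands, was at -2.93 ± 0.39 and -2.30 ± 0.32, and the G1 cyclin gene CLN2 at -2.66 ± 0.32 and -2.22 ± 0.26. Camera gave adjusted p = 0.0023 and 0.028 (adjusted p = 0.402 and 0.408 with an estimated correlation), and the Z100 call ended without Z100 50 °C replicate 1 (adjusted p = 0.051).

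The log2 CPM of each gene was centred on its mean over libraries. Per library, the median of chromosome III genes was taken minus that of genes outside it and the chromosome VII segment. This difference lay between -0.376 and -0.127 in Z100 and between 0.249 and 0.385 in XH7. The genes of the chromosome VII segment were chosen for being higher in Z100 in these same libraries, so a separation of the strains there follows in part from that choice. For this segment the same measure at 30 °C lay between 0.303 and 0.337 in Z100, against -0.222 and -0.21 in XH7. At 50 °C it lay between 0.058 and 0.198 in Z100, against -0.49 and -0.383 in XH7. A loss of 1 of 3 copies would give -0.585 and a gain from 2 to 3 copies 0.585; the ploidy of both strains is not given in the labels, and no DNA data were used. HSF1, the gene of the main heat shock transcription factor (368753 to 371254), lies in the chromosome VII segment, with 42.2 ± 1.47 and 81.7 ± 15.8 CPM in XH7 and Z100 at 30 °C (log2 fold change 0.95 ± 0.37, adjusted p = 0.078, edgeR) and 157 ± 67.9 and 219 ± 98.6 CPM at 50 °C (0.48 ± 0.36, adjusted p = 0.436, edgeR), not called at either temperature.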
